A study of Mus musculus with 4 samples.

How the data were processed

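In situ Hi-C was measured in CD4+CD8+ double positive thymocytes of 4 male C57BL/6 mice, 2 controls (Suv39h1+/y Suv39h2+/-) and 2 double knockouts (Suv39h1-/y Suv39h2-/-, here Suv39DKO), and each library comes from its own mouse per the labels. Per the labels, the libraries were sequenced as paired-end 81 bp reads on a NextSeq instrument and processed on the mm10 build. The aligner, the read pair filters, the removal of duplicates and the counting tool are not given in the sources used here. The authors deposited 1 symmetric sparse matrix per library, whose values are raw contact counts (read pairs) per pair of genomic regions, per the file headers and the whole-number values, and 1 list of 53357 regions with a median width of 50004 bases. The libraries held 94333847 and 159086262 contacts in controls and 119530075 and 113319181 in Suv39DKO, a 1.69-fold range of depth.

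The 51425 regions on autosomes and X were analysed, without 25 wide regions at unsequenced gaps. Contacts that touch chromosome Y, chromosome M or unplaced contigs (0.314% to 0.373% of each library) stayed out of the main comparisons and are described in the closing section. Regions were put in bins of 0.25 Mb, 0.5 Mb or 1 Mb by their midpoints. Genes came from a RefSeq annotation of GRCm38.p6, the same build, and all 221 entries of the gene lists were found in it.

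Compartment scores were the first eigenvector of the correlation matrix of balanced observed/expected contacts per chromosome and library at 0.25 Mb, with the sign set so that gene-dense bins are positive, scaled to unit root mean square per chromosome. Bins under 0.25 of the median coverage were left out (239 of 10299). Scores were compared by limma 3.58.1 with the Benjamini and Hochberg adjustment at 0.05, and lists by camera in the same package with a fixed correlation of 0.01 and with an estimated one. A bin crossed where its adjusted p was under 0.05 and the means of the groups had opposite signs. Compartment strength is log2 of the A to A times B to B over the squared A to B mean observed/expected contacts, between the top and bottom 20% of bins ranked on the 4 libraries summed. Expected contacts came from the mean at each distance within chromosomes and from the bins' trans totals between chromosomes. Chromosome ends were the first and last 5 Mb of covered bins of each autosome, and family clusters were bins with at least 3 genes of a family. Values per library were compared by an exact permutation test of the difference of group means, which with 2 against 2 cannot go below 0.333.

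Raw counts were tested by edgeR 4.0.16 quasi-likelihood fits with group as the only term. Pairs of 50 kb regions on 1 chromosome needed a mean count of at least 10 (583020 pairs, which hold 23.8% to 25.6% of the cis contacts), pairs of 1 Mb bins on different chromosomes a mean of at least 5 (2590549 pairs, 94.3% to 95.5% of the trans contacts), and both were normalized with loess offsets of span 0.3. Above 100000 rows the dispersion trend was fitted on that many rows spread evenly over abundance and interpolated. Insulation was read from the contacts that join the 10 regions before and the 10 after each region, and chromosome pairs from their summed contacts, both with TMM factors. DESeq2 1.42.0 was the second test. Other tools were R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

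The tests, the alternatives, the gene lists and the rule for naming were fixed before the data were examined, apart from additions made after seeing the data, the contact preference for fixed A over fixed B bins and compartment strength with bins ranked by either group alone. The tests of technical causes were written later, in part after the results were seen, as the closing section says. The alternatives covered normalization, filters, bin sizes, scaling, tests, depth, the replicate block and leaving out each library, where a group left with 1 library was assumed to vary like the other. By the rule, the text names up to 15 gained and 15 lost compartment bins by size of change with both Suv39DKO mice outside the range of both controls and at most 1 per 2 Mb, the 10 higher and 10 lower cis and trans pairs and the 5 higher and 5 lower insulation regions with the largest fold changes, and members of the fixed lists. Which of these pairs and which members of the lists to name, and the runs of crossed bins and trans hubs, were picked after their values were seen. Afterwards 4 of the list genes were taken out of the text for reasons unrelated to their values, 2 of them with a change of sign in contact preference, and they still count in their lists. Contacts of named pairs are given as counts per library, since few contacts leave a fold change imprecise.

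The scripts were tested on simulated data. Among 100 pairs or regions changed 2-fold, 19 cis pairs, 1 trans pair and 100 insulation regions were recovered, with 1, 0 and 13 false calls, and among chromosome pairs 10 of 10 with 7 false calls, 10.6% of unchanged pairs falling under p of 0.05. A score change of 0.2 was recovered in 63 of 100 bins and of 0.5 in 96, with 8 false calls. A simulated compartment strength of 3.2 came back as 3.21 between chromosomes and 2.60 within them, and an end enrichment of 0.5 as 0.42.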

Results

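Double positive thymocytes of 2 Suv39DKO mice, which lack the histone H3 lysine 9 methyltransferases encoded by Suv39h1 and Suv39h2, were compared with those of 2 control mice (n = 2 per group in every comparison below). The 50 kb region that holds Suv39h1 had 24.9 and 24.4 CPM (contacts scaled to equal library totals) in the Suv39DKO libraries and 27.0 and 27.1 in the controls (log2 ratio -0.13). The region that holds Suv39h2 had 35.6 and 34.9 against 41.8 and 41.0 (log2 ratio -0.23). Of all covered regions, 8.83% had a lower ratio than the Suv39h1 region and 2.00% a lower ratio than the Suv39h2 region. Contacts summed over whole regions cannot show the deletions, so these values check nothing about the genotype.

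A chromatin (gene dense) and B chromatin (gene poor) were less separated along chromosomes in Suv39DKO thymocytes. Contacts between A and B bins of 0.25 Mb stood at log2 observed/expected -1.73 and -1.73 in Suv39DKO against -2.49 and -2.45 in controls. Contacts among A bins stood at 0.76 and 0.75 against 0.92 and 0.92, and contacts among B bins at 0.79 and 0.80 against 1.00 and 0.99. The strength of compartment contacts, the sum of the A to A and B to B values less 2 times the A to B value, was 5.02 and 5.01 against 6.91 and 6.81 (difference -1.85, standard deviation 0.01 in Suv39DKO and 0.07 in controls, exact permutation p = 0.333, the smallest possible with 2 against 2). Between chromosomes B to B contacts were at 0.80 and 0.75 against 1.14 and 1.08, and A to B contacts at -1.05 and -0.97 against -1.30 and -1.22. A to A contacts between chromosomes did not separate the groups (0.57 and 0.56 against 0.56 and 0.56), but lay lower in Suv39DKO with 0.5 Mb bins (0.52 and 0.51 against 0.54 and 0.54) and higher with 10% of bins (0.60 and 0.58 against 0.58 and 0.58). Strength between chromosomes was 3.46 and 3.26 against 4.31 and 4.08 (difference -0.83, exact permutation p = 0.333).

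**Figure D1:**
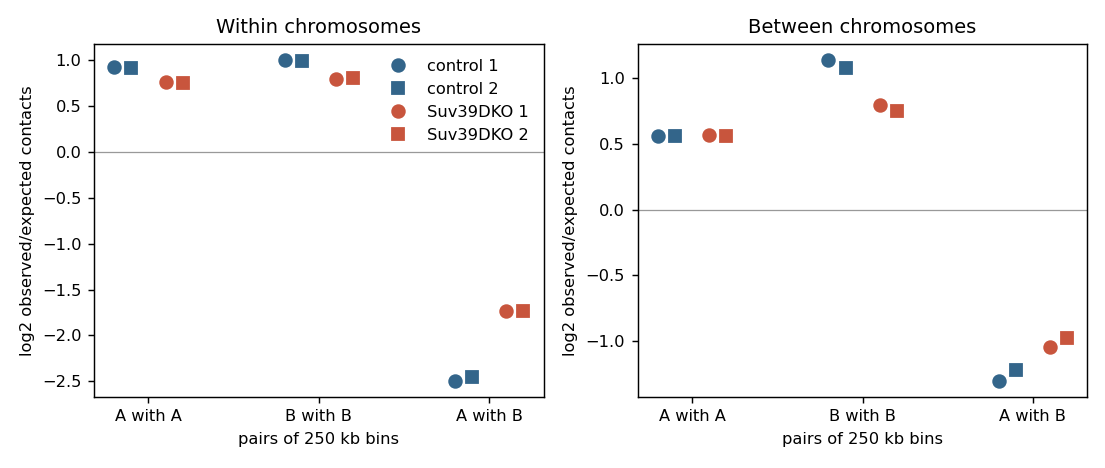
Contacts among A bins, among B bins and between A and B bins in each library, within chromosomes (left) and between chromosomes (right), as log2 observed/expected. Circles and squares are the 2 mice of each group.

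Contacts within chromosomes lay farther apart in Suv39DKO. Of cis contacts, 47.1% and 47.0% spanned more than 10 Mb in Suv39DKO against 43.2% and 43.5% in controls (difference 3.70 percentage points, exact permutation p = 0.333). Both Suv39DKO libraries stood above both controls on 20 of 20 chromosomes, by 0.996 to 4.84 points. Contacts from 0.1 to 1 Mb made up 15.9% and 16.1% against 17.5% and 17.6%, and contacts from 1 to 10 Mb 17.3% and 17.5% against 19% and 19.3%. Leaving out distance classes with few pairs of regions, the largest loss per pair lay between 1.23 and 1.55 Mb (mean log2 -0.21), and pairs more than 151 Mb apart had a mean log2 of 0.99 over controls. The share of all contacts that joined different chromosomes overlapped between groups (28.4% and 29.2% against 27.8% and 28.6%, exact permutation p = 0.667).

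**Figure D2:**
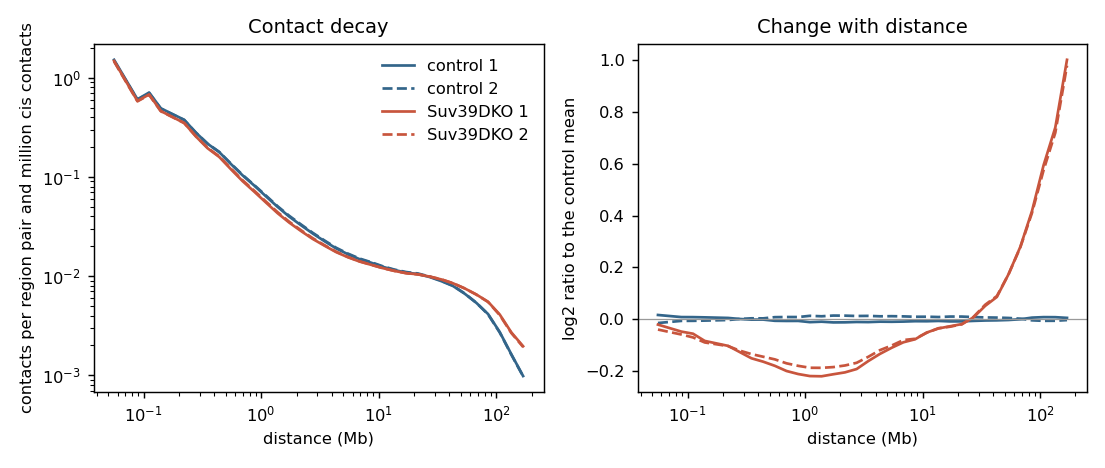
Contacts per pair of regions by distance in each library (left) and the log2 ratio of each library to the mean of the controls (right).

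Single regions changed sides between the compartments, more often out of A than into it. Of 10060 bins of 0.25 Mb, the compartment score rose in 6199 and fell in 2483 (limma, adjusted p under 0.05), and in 568 it crossed from A to B against 122 from B to A. The split between rises and falls depended on the scaling and on the measure: 3279 rose and 2881 fell after quantile normalization, with 319 crossings to B and 316 to A, and 4155 rose and 5048 fell when bins were scored by their contact preference for fixed A over fixed B bins, a measure chosen after seeing the data, with 549 crossings to B and 103 to A. By that preference, 4452 of 5057 bins that were A in controls fell and 193 rose, while 3962 of 5003 that were B in controls rose and 596 fell. The score itself rose in 2632 of those A bins and fell in 1664. Bins that crossed to B held few genes (1.34 per bin, against 3.54 in bins that stayed A). Bins that crossed to A held more genes (2.18 per bin) than bins that stayed B (0.844). These classes also differed in control score, with means of 0.38 against 1.01 for A bins and -0.30 against -0.96 for B bins. Gene counts were not matched on score, so a link with crossing itself was not tested. The score followed gene count more closely in Suv39DKO on 20 of 20 chromosomes, with a mean correlation of 0.510 and 0.510 against 0.464 and 0.461.

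**Figure D3:**
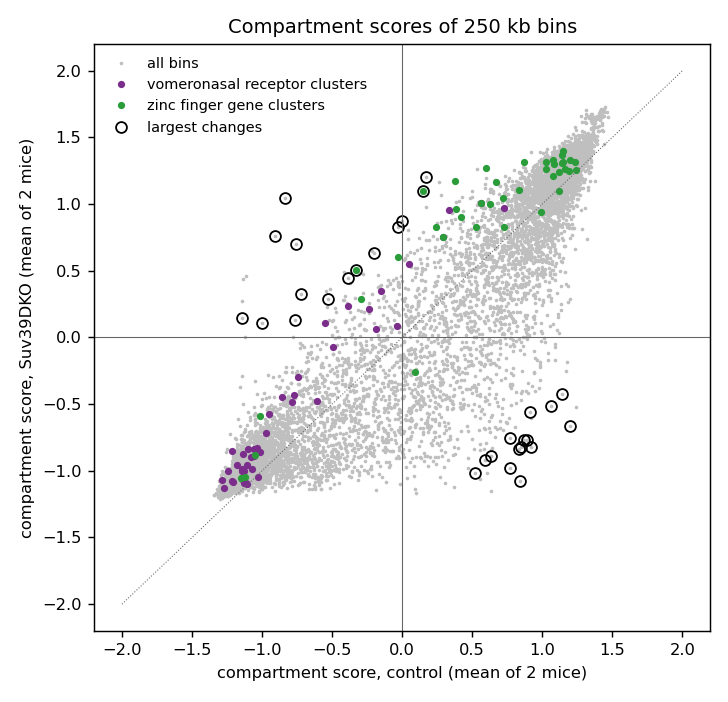
Compartment score of each 0.25 Mb bin in controls and in Suv39DKO. Coloured points are bins with at least 3 genes of a family, and circles mark the bins with the largest gains and losses.

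The 15 largest losses of A score included 11 bins with named genes. The bin of Sugct on chromosome 13 went from 0.84 to -1.07 (change -1.92), the bin of Slc7a11, which encodes a cystine transporter, from 1.20 to -0.67 (change -1.86), and the bin of Chrm3, a muscarinic receptor, from 0.92 to -0.82 (change -1.74). The bins of Pdgfc, a growth factor, Fgf13 and Magi2, a scaffold protein, changed by -1.67, -1.67 and -1.66. The bins of Adgrl2, an adhesion receptor, and Angpt1, a ligand of endothelial cells, changed by -1.56 and -1.53, and those of Slc12a2, an ion transporter, and Dmd, which encodes dystrophin, by -1.53 and -1.47. The bin of Sox6, a transcription factor, changed by -1.58, but the 2 Suv39DKO mice differed there (standard deviation 0.51). Bins without a protein-coding gene fell at 36.8 Mb on chromosome 12 (change -1.75), 66.0 Mb on chromosome 6 (-1.64), 50.5 Mb on chromosome 2 (-1.54) and 61.5 Mb on chromosome 15 (-1.51). The longest runs of crossed bins covered chromosome 13 from 16 to 17.5 Mb with Inhba, an activin subunit, and Sugct, chromosome 3 from 148 to 150 Mb with Adgrl2, and chromosome 8 from 81.2 to 82.7 Mb with Inpp4b and Il15, which encodes a cytokine (6 bins each). A run of 5 bins on chromosome 15 from 60.7 to 62.0 Mb held Myc, a growth regulator. The largest adjusted p among these bins was 0.00252, and every one of them also fell in contact preference.

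The 15 largest gains of score included 3 bins with zinc finger genes. Near the start of chromosome 12, the bin at 20.8 Mb went from -0.84 to 1.05 (change 1.88), the bin at 18.5 Mb from -0.91 to 0.76 (change 1.67) and the bin at 23.0 Mb from -1.14 to 0.14 (change 1.29). The first bin of chromosome 11, with Sfi1, a centrin-binding protein gene, Eif4enif1 and Drg1, went from -0.76 to 0.70 (change 1.46), and the first bin of chromosome 12, with Rab10, a small GTPase gene, from -0.39 to 0.45 (change 0.83). Zinc finger clusters with Zfp712, Zfp708 and Rsl1 on chromosome 13 (0.15 to 1.10, change 0.96), Zfp944, Zfp758 and Zfp946 on chromosome 17 (-0.33 to 0.51, change 0.84) and Zfp990 and Zfp980 on chromosome 4 (-0.53 to 0.29, change 0.82) rose. The bin at 36.7 Mb on chromosome 18 with the protocadherin genes Pcdha1 to Pcdha9 rose from 0.00 to 0.87. The bins of Ice1 and Adamts16 (change 1.05), Gpatch2 (1.04) and Bicc1 and Tfam, a mitochondrial transcription factor (0.89), rose too, as did a bin at 122 Mb on chromosome 1 (1.11) and a bin at 65.0 Mb on chromosome 13 (0.83). The bin of the immunoglobulin kappa constant gene Igkc rose from -0.03 to 0.83. All 15 of these bins also rose in contact preference.

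**Figure D4:**
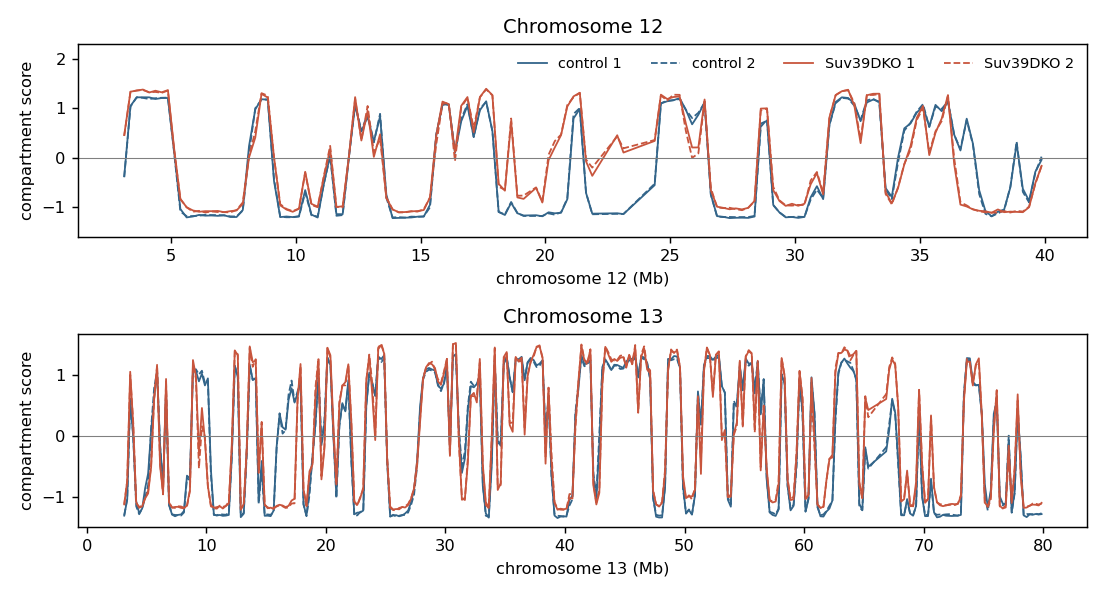
Compartment score along the start of chromosome 12 and along chromosome 13 in each library. Bins with low coverage are left out, and lines join the bins on either side.

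Vomeronasal receptor and zinc finger clusters passed the list test toward A, and Hox clusters passed it away from A, with a fixed correlation between bins but not with an estimated one. Of 44 bins with at least 3 vomeronasal receptor genes, which serve the detection of pheromones, 40 rose and 0 fell (4 did not pass, and the counts were the same adjusted over the list alone), with a mean change of 0.26 (limma camera, adjusted p = 0.000401, and 0.612 with an estimated correlation). Of 40 zinc finger bins, 36 rose and 2 fell (36 and 2 over the list alone), with a mean change of 0.30 (adjusted p = 0.000727, and 0.612 with an estimated correlation), and 3 crossed to A and 1 to B. Of 5 Hox bins, which hold regulators of body axis identity, 0 rose and 4 fell (0 and 4 over the list alone), with a mean change of -0.29 (adjusted p = 0.00988, 0.612 with an estimated correlation, and 0.0807 with 0.5 Mb bins). By contact preference, the vomeronasal bins rose in 41 and fell in 0, the zinc finger bins rose in 19 and fell in 17, and the Hox bins fell in 5 of 5. Of 140 olfactory receptor bins, 107 rose and 22 fell (107 and 23 over the list alone), with no call for the list (limma camera, adjusted p = 0.0780). Vomeronasal bins (36 of 44) and olfactory bins (106 of 140) were mostly B. Over all 5003 bins that were B in controls, the score rose in 3567 and fell in 819, with a mean change of 0.06. Their contact preference changed by 0.67 on average, against 0.87 for the vomeronasal bins. Neither list was tested against B bins alone.

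Contacts between vomeronasal receptor clusters on different chromosomes were fewer. Their log2 observed/expected was 0.35 and 0.24 in Suv39DKO against 0.83 and 0.79 in controls (401 and 372 contacts against 382 and 666, exact permutation p = 0.333). With bins of at least 1 gene it was 0.42 and 0.41 against 0.79 and 0.70. Of the 44 vomeronasal bins with at least 3 genes, 36 were B. B to B contacts between chromosomes changed by -0.33 in general, against -0.52 for these clusters and -0.33 with bins of at least 1 gene. A loss beyond the general one was not tested. Zinc finger clusters stood at 0.60 and 0.59 against 0.66 and 0.72 with bins of at least 3 genes, and the groups overlapped with bins of at least 1 gene (0.32 and 0.30 against 0.30 and 0.31). Olfactory receptor clusters stood at 0.09 and 0.10 against 0.15 and 0.17, and with bins of at least 1 gene at 0.02 and 0.05 against 0.05 and 0.06. Hox clusters (9 to 23 contacts per library), keratin, defensin, cytochrome P450 and serpin clusters did not separate the groups with bins of at least 3 genes, though cytochrome P450 clusters lay higher in Suv39DKO with bins of at least 1 gene (0.23 and 0.19 against 0.16 and 0.10).

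**Figure D5:**
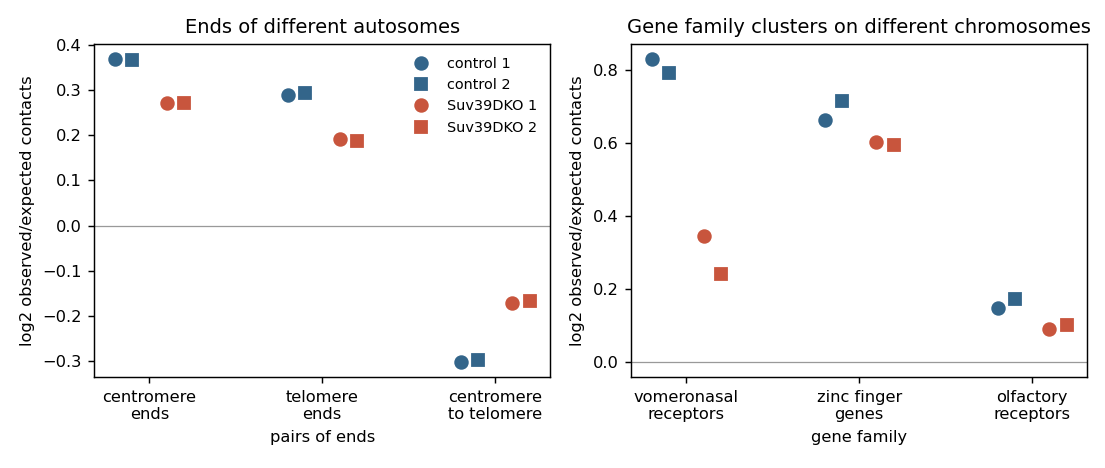
Contacts between ends of different autosomes (left) and between gene family clusters on different chromosomes (right) in each library, as log2 observed/expected.

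Genes of double positive thymocytes kept A scores. Of 35 bins of the double positive list, 27 rose and 5 fell in score (27 and 5 over the list alone), with a mean change of 0.11 and no call for the list (adjusted p = 0.0780). The bins of Cd4 and Cd8a, the coreceptors that define the cells, changed by 0.28 and 0.28, those of Rag1, which rearranges the receptor loci, and Zap70, a receptor kinase, by 0.28 and 0.32, and that of Bcl11b, a T cell transcription factor, by 0.27. After quantile normalization 21 of the 35 bins rose and 6 fell, but in contact preference, another measure, 1 rose and 32 fell (Cd4 -0.65, Cd8a -0.59, Rag1 -0.63, Zap70 -0.94, but Bcl11b 0.49). Bcl6, a transcriptional repressor, Cd1d1, which presents lipids to natural killer T cells, and Satb1, a chromatin organizer, fell in score (-0.44, -0.38 and -0.19) and in preference (-1.48, -0.91 and -0.84).

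Some bins with genes of other stages and lineages crossed to B, and these crossings were not tested against the share over all bins. Over all bins, 568 of 5057 that were A in controls crossed to B. Most genes named below come from bins that fell. More bins rose than fell in score in each list described here except the erythroid one. Crossings to B were 2 of 22 bins in the mature T cell list, 2 of 17 in the B cell list and 1 of 22 in the progenitor list. They were 2 of 17 in the stroma list, 1 of 8 in the erythroid list and 0 of 18 in the myeloid list. In the mature T cell list 12 bins rose and 8 fell of 22, and the bins of Il7r, the interleukin 7 receptor gene, and Zbtb16, which directs natural killer T cells, crossed from 0.59 to -0.45 and from 0.56 to -0.44. Gzmb, a cytotoxic protease gene, fell by 0.38 and Cxcr3, a chemokine receptor gene, rose by 0.32 but fell in contact preference (-1.14). In the B cell list 10 rose and 4 fell of 17, and the bins of Ms4a1, which encodes CD20, and Bank1 crossed from 1.04 to -0.17 and from 0.70 to -0.02, while Pax5, which fixes B cell identity, fell by 0.46. In the progenitor list 13 rose and 6 fell of 22, with Cd34 crossing from 0.29 to -0.25 and Bcl11a and Mef2c going from -0.58 to -1.09 and from -0.53 to -1.07 within B. In the stroma list 8 rose and 6 fell of 17, with Krt5 crossing from 0.42 to -0.54, Col1a2 from 0.53 to -0.40, and Col1a1 and Pdgfra falling by 0.71 and 0.44. In the erythroid list 3 rose and 3 fell of 8, with the beta globin gene Hbb-bs going from 0.00 to -0.84. In the myeloid list 13 rose and 2 fell of 18, with a gain at Adgre1 (0.42) and a fall at Siglech (-0.20). In contact preference, 0 bins rose and 21 fell in the mature T cell list, 0 and 16 in the B cell list, 0 and 21 in the progenitor list, 1 and 15 in the stroma list, 0 and 8 in the erythroid list and 1 and 16 in the myeloid list. After quantile normalization the counts in the same order were 4 and 8, 5 and 5, 5 and 9, 3 and 6, 3 and 4, and 7 and 5. Over each list alone the counts by score were the same, and none of these lists passed (adjusted p from 0.269 to 0.913).

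Genes of the heterochromatin machinery rose in score in 23 of 27 bins and fell in 2 (23 and 2 over the list alone), with a mean change of 0.16 (adjusted p = 0.0525). Trim28, the corepressor of zinc finger proteins, and Kdm4c, a histone demethylase gene, rose by 0.62 and 0.53, and in preference by 0.51 and 0.52. The bins of Suv39h1 and Suv39h2 rose by 0.28 and 0.20 (Suv39h1 -0.80 in preference). Hells, a remodeller of methylated DNA, fell by 0.22 (0.10 after quantile normalization), and Cbx5, which encodes heterochromatin protein 1 alpha, fell by 0.11 (0.0636 with 0.5 Mb bins). Architecture genes such as Ctcf rose in 12 of 14 bins and fell in 0, and housekeeping genes rose in 16 of 20 and fell in 1 (the same counts over each list alone, adjusted p = 0.0736 and 0.0649). By preference 23 of the 27 machinery bins fell, as did 12 of the 14 and 18 of the 20. Of 7 bins of antigen receptor constant genes, 6 rose and 0 fell (6 and 0 over the list alone, adjusted p = 0.144, but 3 rose and 4 fell in preference), with Igkc at 0.86 and the gamma gene Trgc1 at 0.54.

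Local insulation changed widely and in both directions. Rises and falls are relative, since TMM factors centred them. Contacts from 0.1 to 1 Mb made up less of the cis contacts in Suv39DKO, and this general fall was removed. Of 50509 regions of 50 kb, contacts across the region rose in 11131 and fell in 12387 (edgeR, adjusted p under 0.05, and 7263 rose without control replicate 2). They rose in 6628 and fell in 5245 of 23811 regions in A, and rose in 4449 and fell in 7107 of 26032 in B. The largest gains were at Aacs and Tmem132b on chromosome 5 (log2 fold change 1.79, standard error 0.10), at 36.8 Mb on chromosome 18 beside the protocadherin genes (1.49), at 24.1 Mb on chromosome 12 (1.45), at 112 Mb on chromosome 8 (1.39) and at Pglyrp4, an antibacterial protein gene of the epidermal cluster on chromosome 3 (1.38). The largest losses were at 50.1 Mb on chromosome 15 (-1.76), 50.5 Mb on chromosome 3 near Slc7a11 (-1.57), 15.6 Mb on chromosome 14 (-1.55), Magi2 (-1.41) and 81.8 Mb on chromosome 10 (-1.36). Among list genes, crossing contacts rose at Igkc (1.01), Trac and Trdc, the alpha and delta receptor genes (0.88 and 0.85), S100a8, a neutrophil gene (0.87), and Adgre1 (0.73). They fell at Bcl6 (-0.60), Bcl11a (-0.58), Ms4a1 (-0.55), Krt5 (-0.42), Il7r (-0.41) and Zbtb16 (-0.35). At Cd4, Rag1 and Bcl11b they did not pass (adjusted p = 0.0891, 0.310 and 0.758).

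Nearby pairs of 50 kb regions on the same chromosome lost contacts more often than they gained them, after loess offsets. The pairs with enough contacts to be tested lay a median of 350 kb apart, and 97.7% lay within 2 Mb. Of 583020 pairs, contacts rose in 2289 and fell in 5142 (edgeR, adjusted p under 0.05). Counts summed to 0.25 Mb gave 121947 higher and 95195 lower of 1689323 pairs, DESeq2 gave 3 higher and 101 lower, and leaving out 1 library at a time gave 330 to 834 higher and 1550 to 2318 lower. Among A regions 970 pairs rose and 3064 fell, between A and B 511 and 1249, and among B regions 805 and 829. At 0.25 Mb, pairs between A and B rose in 11.1% and fell in 5.99%, pairs among A bins rose in 4.09% and fell in 7.77%, and pairs among B bins rose in 6.50% and fell in 3.45%. Most pairs at 0.25 Mb (1349659) lay over 10 Mb apart, and 6.42% of these rose and 4.65% fell. From 0.5 to 2 Mb apart, pairs between A and B rose in 23.3% and fell in 13.7% at 0.25 Mb, but in 0.482% and 2.13% at 50 kb. Contacts nearly vanished between 2 regions at 49.6 and 50.3 Mb on chromosome 15 (25 and 28 in controls, 2 and 0 in Suv39DKO, adjusted p = 3.08e-8), between Tafa2 and Atp23 on chromosome 10 (25 and 20, then 2 and 0), between Agbl1 and Ntrk3, a neurotrophin receptor gene, on chromosome 7 (18 and 27, then 0 and 2) and between Dock10 and Nyap2 on chromosome 1 (20 and 23, then 0 and 2). Adgra3 and Ppargc1a, a metabolic coactivator gene, went from 13 and 28 to 1 and 1, and Cfap20dc and Fhit from 14 and 24 to 2 and 0. Contacts rose between Ccdc93 and a region at 122 Mb on chromosome 1 (3 and 4, then 21 and 20), between 173 and 174 Mb on chromosome 2 (2 and 6, then 20 and 27), between Sorcs2 and Evc (1 and 6, then 24 and 12) and beside Wnt7b, a signalling ligand gene (3 and 6, then 25 and 20).

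Pairs of 1 Mb bins on different chromosomes changed in both directions. Of 2590549 pairs, contacts rose in 1507 and fell in 1545 (edgeR, adjusted p under 0.05), while 0 rose and 0 fell without either control (edgeR, 72441 and 67902 at unadjusted p under 0.05 without control replicate 1, 65244 and 60108 without control replicate 2). TMM factors gave 1819 higher and 12892 lower, DESeq2 47 and 1906, a mean count of at least 10 gave 4966 and 5294, and no filter 539 and 316. In the main test 1036 pairs among A bins rose and 1258 fell of 717612 (median log2 fold change -0.06). Between A and B 327 rose and 265 fell of 1174244, and among B bins 144 and 21 of 698518 (median 0.03). These counts were not corrected for the coverage of each bin, unlike the observed/expected values above. The first bin of chromosome 11, from 3.10 to 4 Mb with Sfi1 and Drg1, took part in 404 of the rises and 105 of the falls. The bin at 39 Mb on chromosome 17 had 94 rises and 2 falls, and the bins at 80 Mb on chromosomes 10 and 15 had 52 and 2 and 50 and 6. Falls gathered at 135 Mb on chromosome 1 (0 rises, 73 falls), 15 Mb on chromosome 14 (0 and 64), the bin of Slc7a11 on chromosome 3 (6 and 58) and 137 Mb on chromosome 4 (2 and 58). The Slc7a11 bin gained contacts with the bin of Apob, which encodes a lipoprotein of the liver and gut, on chromosome 12 (1 and 2 in controls, 23 and 18 in Suv39DKO, adjusted p = 0.000482) and with a bin at 52.0 Mb on chromosome 8 (0 and 0, then 6 and 14). The bin of Myc lost contacts with the bin of Tle3, a corepressor gene, and Kif23 on chromosome 9 (17 and 30, then 1 and 3, adjusted p = 0.000487). The first bin of chromosome 11 lost contacts with a bin at 25 Mb on chromosome X (13 and 10, then 1 and 0).

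Whole chromosomes and their ends also changed partners. Of 190 chromosome pairs, contacts rose in 47 and fell in 46 (edgeR, adjusted p under 0.05, but 8 to 47 and 10 to 43 with 1 library left out). The pairs with the largest falls were 11 with 12 (log2 fold change -0.16), 12 with 17 (-0.14) and 2 with 17 (-0.13), and those with the largest rises 7, 8 and 2 with X (0.13, 0.11 and 0.11). Contacts between the centromere-proximal 5 Mb of different autosomes were fewer, at log2 observed/expected 0.27 and 0.27 in Suv39DKO against 0.37 and 0.37 in controls (difference -0.10, exact permutation p = 0.333), and both Suv39DKO libraries lay below both controls in 111 of 171 chromosome pairs and above in 23. For tests of 1 Mb bins the ends were drawn more widely and with X included, so those sets of bins differ from the 5 Mb ends. Of 5930 tested pairs between such centromere-proximal bins, 33 rose and 18 fell (edgeR, adjusted p under 0.05, median log2 fold change -0.14). Between such telomere-proximal bins, 9 of 5537 pairs rose and 2 fell (median -0.06). With 2 Mb ends of autosomes, log2 observed/expected between centromere-proximal ends differed by -0.03 (0.55 and 0.56 against 0.59 and 0.57). The next windows stood at 0.22 and 0.22 against 0.38 and 0.38 from 5 to 10 Mb and at 0.25 and 0.25 against 0.36 and 0.36 from 10 to 15 Mb. Telomere-proximal ends stood at 0.19 and 0.19 against 0.29 and 0.29, and centromere-proximal ends met telomere-proximal ends more often (-0.17 and -0.17 against -0.30 and -0.30). Among chromosomes 12, 15, 16, 18 and 19, which carry ribosomal DNA near the centromere, the groups overlapped (0.22 and 0.25 against 0.24 and 0.24), while Suv39DKO lay higher with 2 Mb ends (0.65 and 0.71 against 0.61 and 0.57) and lower with 10 Mb ends (0.23 and 0.25 against 0.30 and 0.30) and without the 5% of bins with the lowest coverage (0.18 and 0.20 against 0.21 and 0.21).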

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

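The tests of random ligation, of cell composition, of low coverage and of X coverage were chosen after the result was seen, and the others were written before. The test of cell composition was also changed after its value was seen: judged by the compartment score alone, as first run, it argued against fewer double positive cells, and the contact preference was added to it only then, which left it undecided.

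Chromosome Y and unplaced contigs lie outside the main comparisons, and both held more contacts in Suv39DKO than in either control. Chromosome Y had 1484 and 1510 CPM (contacts scaled to equal library totals) in Suv39DKO against 1237 and 1284 in controls, a mean difference of 237. Unplaced contigs had 2169 and 2191 against 1880 and 1904, a mean difference of 288. With 2 libraries per group the exact permutation p of each was 0.333.

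The rise on chromosome Y and unplaced contigs went with that of the start of chromosome 11. A rise of coverage with unchanged partners was tested by the balance of A over B partners on other chromosomes. Beyond the genome-wide change, its log2 odds moved by 0.54 for chromosome Y, 1.65 for unplaced contigs and 2.35 for the start of chromosome 11. These values argue against a rise of coverage alone. The start of chromosome 11 had already crossed to A in score, so its value is not independent of that result. Another mix of male and female cells would lower chromosome X, whose log2 ratio was -0.0102. Reads shared between repeats were not tested and stay open beside the genotype. Mean log2 odds went from -1.20 to 0.25 for unplaced contigs and from -1.20 to 0.95 for the start of chromosome 11. Partners of chromosome Y stayed mostly B (-0.99 to -0.65). Partners were summed over all contigs, so the shift of the contigs may rest on few of them. The shift to A partners may reflect a change of compartment of the contigs and of the start of chromosome 11. That hypothesis was found and tested on the same data.

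Compartment contacts were weaker in Suv39DKO. A larger share of random ligations would lower A to A contacts between chromosomes along with B to B contacts, but the lowest Suv39DKO value lay 0.19 above the value predicted from the B to B loss. With every library thinned to the depth of the shallowest the difference in strength within chromosomes was still -1.84. The ranked bins came from the full libraries there, and random thinning leaves mean ratios nearly unchanged, so that test could not show an effect of depth. The Suv39DKO libraries (119530075 and 113319181 contacts) lay between the controls (94333847 and 159086262) in depth but below both in strength, which argues against depth. Fewer double positive cells among the sorted cells cannot be told apart from the genotype, since the bins of their genes rose in score by 0.11 on average (all A bins -0.06) but fell in contact preference by 0.78, close to the fall of 0.81 over all A bins. The loss of B to B contacts relative to the expected value may be biological, without the histone methyltransferases, but cell composition stays open. It was not a loss in raw counts, where 144 B to B pairs of 1 Mb bins between chromosomes rose and 21 fell.

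Contacts between centromere-proximal ends of different chromosomes were fewer in Suv39DKO. A general loss of contacts between B regions was tested by taking the expected value per pair of score deciles in each library, and the difference stayed at -0.093, which argues against it as the whole cause. Without the 5% of bins with the lowest coverage it was -0.10, which argues against poorly mapped ends. Telomere-proximal ends changed by -0.10 as well under the score deciles, and the windows from 5 to 10 Mb fell from 0.38 and 0.38 to 0.22 and 0.22, so the change was confined neither to centromeres nor to the ends. Its cause stays open.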

How the results depend on the processing

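Settings fixed before the data were examined are given here where they moved a main result or turned a named value, while small differences that had not separated the groups or passed a test turned in sign more often. Bins ranked by 1 group and the contact preference for fixed A over fixed B bins were chosen after seeing the data. The cause was not tested unless stated.

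Values per library: the share of cis contacts over 10 Mb differed by 4.07 points without contacts inside regions and 3.95 for over 20 Mb. Strength within chromosomes differed by -1.90 with 10% of bins, -1.76 at 0.5 Mb, -2.27 with bins ranked by controls and -1.39 by Suv39DKO, and between chromosomes by -0.999 and -0.59 with the same rankings. Centromere-proximal ends differed by -0.029 at 2 Mb, -0.12 at 10 Mb and -0.10 without low coverage. With bins of at least 1 family gene, olfactory receptors differed by -0.022, vomeronasal receptors by -0.33 and zinc finger genes by 0.0077, the opposite sign.

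Counts (higher and lower): cis pairs were 174 and 1050 with no filter within 2 Mb, 121947 and 95195 at 0.25 Mb, 3 and 101 by DESeq2, and 330 to 834 and 1550 to 2318 with 1 library left out. Trans pairs were 4966 and 5294 with a mean count of at least 10, 539 and 316 with no filter, 47 higher by DESeq2, 12892 lower with TMM, and 0 to 1349 and 0 to 900 with 1 library left out, the 0 being without either control. Compartment bins were 3105 and 1261 at 0.5 Mb, where fewer bins are tested, 3279 higher after quantile normalization and 5048 lower by contact preference. Insulation regions were 6739 higher with windows of 5 regions, 7016 and 8228 by DESeq2, and 7263 to 10574 higher with 1 library left out. Chromosome pairs were 8 to 47 and 10 to 43 with 1 library left out. Lists passing were 0 up and 0 down with an estimated correlation, 5 up after quantile normalization, 0 down at 0.5 Mb and 2 to 4 up with 1 library left out.

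The replicate numbers only share a number, and the deviations of same-numbered libraries correlated at 0.007 for cis pairs, 0.004 for trans pairs, 0.06 for compartment bins, 0.25 for insulation and 0.79 for chromosome pairs. The replicate block gave 3368 higher and 3461 lower trans pairs and 76 and 75 chromosome pairs. It added the machinery list (limma camera, adjusted p = 0.0420) and moved no other count by over 1.5 times. Without the block, that list had an adjusted p of 0.612 by limma camera with an estimated correlation.

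Gene bins that changed sign: in contact preference Suv39h1 (-0.80), Cd4 (-0.65), Cd8a (-0.59), Rag1 (-0.63), Zap70 (-0.94), Notch1 (-1.20), Cxcr3 (-1.14), S100a8 (-0.61), Klf1 (-1.03), Lmna (-0.34), Setdb1 (-0.18), Trac and Trdc (-0.66), Ctcf (-0.83), Stag2 (-0.72) and Gapdh (-0.77), after quantile normalization S100a8 (-0.12) and Hells (0.10), and at 0.5 Mb Cbx5 (0.0636). Crossing contacts turned at Rag1 (0.10) and Trim28 (-0.0110) with windows of 20 regions and at Col1a2 (0.15) with windows of 5, and the cis pair at Fabp4 (-0.0818) at 0.25 Mb.

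On simulated data 19 of 100 cis pairs and 1 of 100 trans pairs changed 2-fold were found. Far fewer pairs were changed there than were called in the data, which makes the adjustment of p stricter. The simulated shares therefore do not give the share of changed pairs found in the data, which is not known. Of the 3 ways to split 4 libraries into pairs, the real one gave 7431 cis calls, 8682 compartment calls and 23518 insulation calls and the other 2 gave 0, which are too few splits to judge chance.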

Other observations

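The test in this part was written before its result was seen.

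Other values are given here. Coverage at equal library totals shifted from A to B bins (log2 ratio -0.07 and 0.09). A bins stood at 235 and 232 in Suv39DKO against 246 and 243 in controls. B bins stood at 165 and 168 against 155 and 158. The log2 ratio was 0.10 in vomeronasal receptor bins, 0.04 in olfactory receptor bins and -0.01 in zinc finger bins, where the groups overlapped. The log2 odds of A over B ends of all trans contacts were 0.47 and 0.42 against 0.67 and 0.63. Raw counts of pairs, chromosome pairs and crossing contacts were not corrected for coverage per bin. The part of this shift in their changes was not tested. Chromosome M had 33.3 and 29.8 CPM (contacts scaled to equal library totals) in Suv39DKO against 28.1 and 30.1 in controls, which overlap. The libraries of a group correlated more closely than those of different groups in compartment score (0.999 in controls and 0.999 in Suv39DKO, 0.952 to 0.955 between groups) and in crossing contacts (0.997 and 0.995, 0.971 to 0.974 between groups), but not in pairs of 1 Mb bins on different chromosomes (0.704 in controls and 0.629 in Suv39DKO, 0.584 to 0.649 between groups). The share of variance that the first eigenvector explained was lower in both Suv39DKO libraries than in both controls on 11 of 20 chromosomes. Its means over chromosomes overlapped, at 52.4% and 51.7% in Suv39DKO against 52.3% and 56.1% in controls. The highest belonged to the deepest library, control replicate 2.

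A bin that crossed from A to B might be an A island drawn toward B surroundings. That predicted lower control scores 1 to 2 Mb to either side of the 568 bins that crossed than beside bins that stayed A matched on control score, but they were higher by 0.25 (mean 0.20, standard deviation 0.61, against -0.05, standard deviation 0.63, permutation p = 0.00001). The matching was imperfect, since the crossing bins themselves averaged 0.38 in controls and the matched bins 0.44. Bins that crossed from B to A had lower flanking scores than matched bins that stayed B, by 0.23 (permutation p = 0.007). The permutations treated bins as separate, though some crossing bins came in runs of adjacent bins that share flanks. Both p-values may therefore be too small. By these means, crossing bins lay in surroundings of their own control compartment more than matched bins did. The lower flanking scores that drawn islands predicted were not seen.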
